A study of Mus musculus with 6 samples.

How the data were processed

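The series holds 6 samples of epididymal white adipose tissue, 3 of Pparg ldi/+ and 3 of litter-matched wild-type male mice, 10 weeks old. Genotype and number come from the sample titles. Per the labels' protocols, each array took the RNA of a single mouse, which was extracted with Tri Reagent, treated with DNase and extracted again with phenol, then biotin-labelled and hybridised to an Affymetrix MOE430v2.0 array.

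The deposited values are linear signal intensities, 1 per probe set and array. Per the submitters' processing notes, MAS5 made them; the notes name it for 2 of the 6 samples, and its version, scaling target and detection calls are not given in the sources used here. The deposited intensities had medians of 59.2 to 69.4 and trimmed means of 201 to 236 per array, so the arrays were near a common scale. No value was missing, and 2 values were exactly 0. Without detection calls, no probe set could be called above or below background.

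Each array was scaled to a mean of 500 after trimming 2% of values at each end, with factors of 2.12 to 2.49. An offset of 32 was added and log2 taken. The log2 values were computed here from the deposited intensities. The offset shrinks differences of dim genes. Of 45101 probe sets, 64 controls were left out. The platform annotation gave 34945 of the others a single gene symbol, 932 several and 9160 none, and only the first were named. Symbols were updated through the gene number for 34741 of them in a RefSeq table of assembly GRCm38.p6, and 204 kept the annotated symbol. That table was used for names and for which genes neighbour each other; no coordinates are given because the files name no genome build.

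A gene was represented by its probe set with the highest mean over the 6 arrays, leaving out cross-hybridising sets (suffix x_at) where another existed. This left 18193 genes. Those whose mean lay below the median of all probe set means, a log2 value of 7.46, were not tested, which left 11201. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, all 6 arrays, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. In the text rose and fell mean past that threshold. Signals are means of the scaled signal ± SD over 3 arrays. Folds come from the log2 differences.

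Before the data were examined, 26 gene lists were fixed, together with the processing alternatives. The 24 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, and adjusted over the lists. By camera 3 lists were higher and 10 lower. None of these calls held (0 of 24) with an estimated correlation, where the smallest adjusted p was 0.255. By fry, which tests whether a list's genes move one way on balance, 5 were higher and 10 lower. For the 10 called lists other than fatty acid and triglyceride synthesis, citrate cycle, and insulin signalling and glucose uptake, the adjusted p was at most 0.00821 in every other alternative that tested them. For those 3 it reached 0.0814, 0.191 and 0.060.

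The genes named were set by a rule fixed at the same time: Pparg, 6 reference genes of adipose tissue, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and the 2 members of each list with the smallest p. Where a few members of a list went against the others or did not pass, they are named as well, and these were chosen after their values were seen.

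The method was tested on simulated data with the genes and array number of this comparison. Of 200 changed genes among 11201, the fit recovered 31.8% at a log2 change of 0.5, 70.1% at 1 and 94.0% at 2, and it called 5 of 11001 unchanged genes. The real comparison called 32.7% of genes. Recovery under Benjamini-Hochberg adjustment depends on the share of changed genes, so these rates do not carry over to it. Camera found the shifted list and called 0 of 25 unshifted ones, with genes simulated as independent.

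The alternatives changed the offset (16, 100, or a floor of 32), the scaling (quantile, or none), the filter on dim probe sets, the variance model, the choice of probe set, the threshold, the set test and the use of the title's number as a block, and left out each array in turn. A comparison of Pparg ldi/+ array 3 alone with the 3 wild-type arrays was added after the data were seen; there the lone sample is assumed to vary like the other group.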

Results

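Transcript levels were measured in epididymal white adipose tissue, the fat pad that lies along the epididymis, of 10-week-old male mice on a mixed C57BL6;129Sv background. The mice carried either 1 copy of an allele of Pparg called ldi, which the labels tie to lipodystrophy, or 2 wild-type copies, and the wild-type animals were litter-matched. Pparg encodes the nuclear receptor that drives adipocyte differentiation. RNA of 3 Pparg ldi/+ mice and 3 wild-type mice was hybridised to 1 Affymetrix MOE430v2.0 array each, and the number of arrays limits the precision. The trimmed mean of the deposited signals lay between 201 and 236 on the 6 arrays. The ratio of the 3' to the 5' probe set was between 1.10 and 1.13 for actin and between 0.749 and 0.814 for Gapdh. Across the 11201 genes tested, an array correlated with the others of its genotype at a mean r of 0.972 to 0.980, and with those of the other genotype at 0.888 to 0.906. These correlations are across genes, which are not independent replicates.

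The comparison of the genotypes asks how the fat pad's transcripts differ when 1 Pparg allele is ldi. Of 21 genes that PPARG activates in adipocytes, 16 fell in Pparg ldi/+ fat, and all 27 macrophage markers tested rose. By limma's camera both lists passed the threshold, and neither did with an estimated correlation (adjusted p = 0.255 for each). Pparg itself fell 2.56-fold, from a signal of 4605 ± 341 (SD, n = 3) in wild type to 1781 ± 104 (SD, n = 3), and every Pparg ldi/+ array lay below every wild-type array. Its log2 difference was -1.35 (95% confidence interval -1.55 to -1.16, SE 0.084, limma adjusted p = 1.04e-05). An exact two-sided permutation test of these 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. Where the probes of Pparg lie relative to the ldi alteration is not given in the sources used here, so the signal does not separate the 2 alleles.

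Of 11201 genes tested, 1831 rose and 1837 fell in Pparg ldi/+ fat, together 32.7%. Differences of 2-fold or more were found for 529 of the genes that rose and 407 of those that fell, and of 8-fold or more for 20 and 21. The groups did not overlap in 5331 genes, 47.6% of those tested, where chance gives 10%. Among the genes past the threshold the groups did not overlap in 3643 of 3668. Folds are on the scale of log2(signal + 32), which understates the change of dim genes. Most genes of a list of epididymal markers were high in Pparg ldi/+ arrays 1 and 2 and not in array 3. With array 3 as the only Pparg ldi/+ array, a comparison added after the data were seen, 730 genes rose and 886 fell, and 1561 of the 3612 called genes still tested were called in the same direction. A fit of 1 array against 3 calls fewer genes at a given size, and Pparg was at -1.26 there.

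Among 6 adipose reference genes fixed beforehand, 4 fell. Adipoq, which encodes the hormone adiponectin, fell 2.25-fold (log2 -1.17, SE 0.134, adjusted p = 0.000266). Lep, the leptin gene, fell 2.22-fold (log2 -1.15, SE 0.156, adjusted p = 0.0007). Cebpa, a transcription factor of adipocyte differentiation, fell 2.13-fold (log2 -1.09, SE 0.056, adjusted p = 4.37e-06), and Slc2a4, the insulin-regulated glucose transporter, fell 2.27-fold (log2 -1.19, SE 0.101, adjusted p = 5.59e-05). Fabp4, an adipocyte fatty acid binding protein, had a log2 difference of -0.15 that did not pass (adjusted p = 0.0761), and quantile normalisation turned it to 0.03. The probe set read for Fabp4 was among the brightest, at 31477 in wild type and 28270 in Pparg ldi/+. Its 3 other probe sets differed by -0.27, -1.19 and -1.83, and the mean of all 4 fell by 0.86. With array weights the brightest probe set passed as well, at -0.17. Ucp1, the uncoupling protein of thermogenic fat, was too dim to be tested, with a signal of 24.3 ± 27.6 in wild type and 185 ± 107 in Pparg ldi/+ (SD, n = 3).

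**Figure D1:**
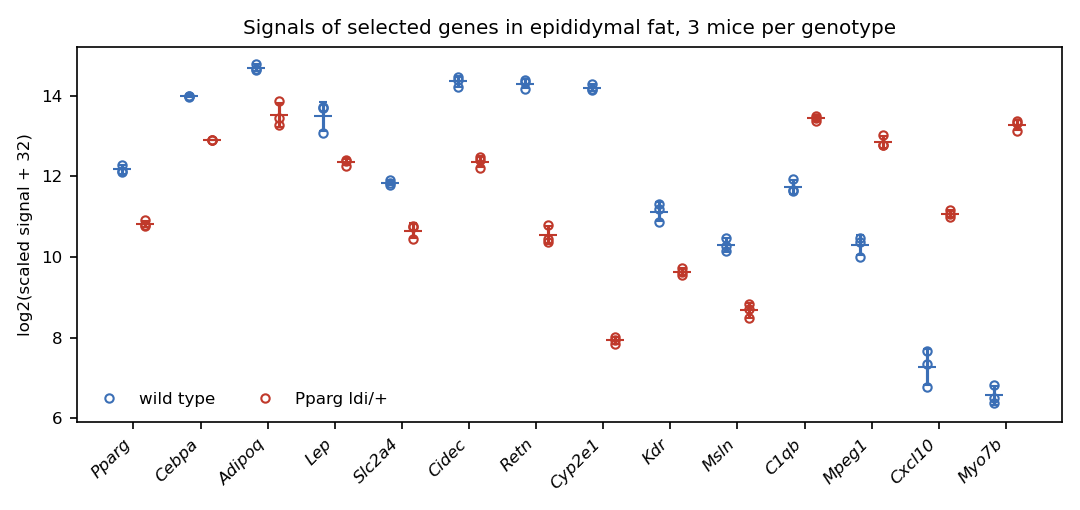
Signals of 14 genes on the 6 arrays. The vertical axis is log2 of the scaled signal plus 32, open circles are single arrays (1 mouse each), and the bar with whiskers gives the mean and SD of the 3 arrays of a genotype. In each gene shown, the 3 Pparg ldi/+ arrays and the 3 wild-type arrays do not overlap; Cyp2e1 has the largest fall and Myo7b the largest rise.

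The 10 largest falls were led by Cyp2e1, a cytochrome P450 enzyme, whose signal was 18917 ± 1117 in wild type and 212 ± 15.2 in Pparg ldi/+ (log2 -6.28, 77.6-fold, adjusted p = 2.61e-09). Tmem45b fell 56.0-fold, Nnat (neuronatin) 31.0-fold, the amino acid transporter gene Slc7a10 26.7-fold and the galactosyltransferase gene B3galt2 24.7-fold. Sfrp5, a secreted antagonist of Wnt signalling, fell 20.9-fold. Acvr1c, which encodes the activin-type receptor ALK7, fell 15.4-fold, and Sncg (gamma-synuclein) fell 15.3-fold. A dimmer probe set of Acvr1c differed by -2.14, and the mean of its probe sets by -3.33 where the one read gave -3.94. D430019H16Rik fell 14.5-fold and Retn, the resistin gene, fell 13.6-fold, from 20258 ± 1587 to 1471 ± 247. The adjusted p of these falls was at most 4.31e-05. The sizes of 2 falls to dim signals depend on the offset and scaling. With 100 added, the log2 difference moved from -4.63 to -3.69 for B3galt2 and from -3.86 to -2.91 for D430019H16Rik, with unscaled values it was -3.93 and -3.17, and for B3galt2 it was -5.35 with a floor of 32. D430019H16Rik was at -4.47 with Pparg ldi/+ array 3 alone.

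The largest rise was that of Myo7b, an unconventional myosin, from 63.4 ± 15.6 in wild type to 9920 ± 868 in Pparg ldi/+ (log2 6.71, 105-fold, adjusted p = 2.28e-08). Its wild-type signal was dim, so the fold depends on the offset: the log2 difference was 5.94 with 100 added and 7.31 with a floor of 32. Robo1, a receptor of Slit ligands, rose 24.4-fold, the cell polarity gene Pard3b 18.8-fold, the chemokine gene Ccl12 18.1-fold, the microtubule-associated Map1b 15.3-fold and the MHC class I gene H2-Q10 15.2-fold. With 100 added, the log2 difference of Ccl12 moved from 4.18 to 3.37. Ints6, a subunit of the Integrator complex, rose 15.7-fold in the probe set read for it, while its 3 other probe sets differed by -0.09, -0.48 and -0.26. With the mean of a gene's probe sets, the log2 difference moved from 3.97 to 0.79 for Ints6, from 4.61 to 2.15 for Robo1, from 4.23 to 3.53 for Pard3b and from 3.94 to 3.12 for Map1b, and all 4 still passed. A dimmer probe set of Pard3b differed by 1.54. The remaining 3 of the 10 were Teddm2, Lcn9 and Cst12, with log2 differences of 4.07, 4.02 and 3.96 and adjusted p of 0.0269, 0.0297 and 0.0337. Their SE was 1.17 to 1.20, and they were high in Pparg ldi/+ arrays 1 and 2 only. All 3 calls ended when any 1 wild-type array was left out, with log2 differences of 4.05, 4.19 and 3.86 without wild-type array 1, 4.05, 4.28 and 4.19 without array 2, and 4.13, 3.60 and 3.84 without array 3. Without Pparg ldi/+ array 3 they passed at 5.76, 5.68 and 5.66. With 100 added the log2 differences were 3.26, 3.38 and 3.05, that of Teddm2 was 4.78 with a floor of 32 and that of Cst12 was 3.30 with unscaled values, all past the threshold. Lcn9 also lost its call without Pparg ldi/+ array 1 (3.28) or array 2 (3.10). In those fits Teddm2 and Cst12 were too dim to be tested. Testing without a filter on dim probe sets ended all 3 calls too, and a variance model with no intensity trend ended those of Lcn9 and Cst12, with no change in the log2 differences.

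Most of the genes that PPARG activates in adipocytes fell. Of 21 tested, 16 fell and none rose (0), and 20 fell when adjusted over the list alone. The median log2 difference was -0.94 (limma camera adjusted p = 6.43e-10). With an estimated correlation the adjusted p = 0.255. Besides Retn, the members that fell included Plin4, a lipid droplet coat protein (3.52-fold lower, adjusted p = 2.05e-06), and Cidec, which promotes large lipid droplets (4.0-fold lower, adjusted p = 2.73e-06). The 5 that did not pass were Gpd1 at -0.51, Cd36 at -0.21, Lpl at -0.17, Fabp4 at -0.15 and Fabp5 at 0.23, named after their values were seen. Cd36, Lpl and Fabp4 were among the list's brightest, with wild-type log2 values of 14.5, 14.7 and 14.9. Adipoq, at 14.7, was as bright and fell. The other probe sets of Fabp4 differed by -0.27, -1.19 and -1.83. The list shares 7 members with the lipolysis and lipid droplet list and 5 with the adipokine list, so the 3 are not independent. With Pparg ldi/+ array 3 alone, 13 of the 21 fell, and the median was -1.07.

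Most adipokine genes and most genes of lipid droplets and lipolysis fell as well. Of 15 adipokine genes tested, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -1.15 (camera adjusted p = 3.53e-06; adjusted p = 0.255 with an estimated correlation). Sfrp5 and Retn led the falls, and the member that rose was Grn, the progranulin gene, at 0.81. Of 18 lipolysis and lipid droplet genes, 14 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 1.23e-06; adjusted p = 0.255 with an estimated correlation). The 2 that rose were the droplet coat genes Plin2 at 0.77 and Plin3 at 0.25, in contrast to Plin4 at -1.82 and Cidec at -2.0. With array 3 alone, 9 of the 15 adipokine genes and 9 of the 18 lipid droplet genes fell, with medians of -1.11 and -0.88.

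Genes of fatty acid and triglyceride synthesis went both ways. Of 24 tested, 13 fell and 4 rose (14 and 4 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.021; adjusted p = 0.593 with an estimated correlation). The acyltransferase genes of triglyceride assembly Gpat3 and Dgat1 fell 4.34-fold and 2.28-fold. The 4 that rose were Elovl6 at 0.91, Fads1 at 0.57, Mlxipl at 0.54 and Acly at 0.50, which elongate or desaturate fatty acids, regulate lipogenic genes or supply acetyl-CoA. The call of this list ended without wild-type array 2, where the median was -0.38.

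Genes of insulin signalling and glucose uptake fell in 10 and rose in 5 of 22 (10 and 6 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.0284; adjusted p = 0.540 with an estimated correlation). Pde3b, the phosphodiesterase through which insulin restrains lipolysis, fell 3.82-fold (adjusted p = 1.17e-05) and the kinase gene Akt2 fell 2.28-fold (adjusted p = 1.3e-05). The 5 that rose were Grb14 at 1.12, Ptpn1 at 1.12, Socs3 at 0.93, Irs2 at 0.51 and Slc2a1 at 0.48. Grb14, Ptpn1 and Socs3 restrain insulin receptor signalling. The list's genes that do so did not all rise, since Grb10 fell, at -0.93 (limma adjusted p = 3.27e-05). The call ended without wild-type array 3 (median -0.18) and when only the brighter 30% of probe sets were tested (median -0.18).

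Most genes of branched-chain amino acid catabolism fell. Of 18 tested, 14 fell and 0 rose, with the same counts adjusted over the list alone, and the median was -0.55 (camera adjusted p = 1.23e-06; adjusted p = 0.255 with an estimated correlation). Mccc2, of leucine breakdown, fell 2.52-fold and Hibch, of valine breakdown, fell 2.39-fold. In the citrate cycle list, 7 of 20 fell and 1 rose, also adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0159; adjusted p = 0.318 with an estimated correlation). Pcx, the pyruvate carboxylase gene, fell 1.76-fold and Idh2 fell 1.61-fold, while the member that rose, Dlat of the pyruvate dehydrogenase complex, was at 0.49. The citrate cycle call ended with the deposited values left unscaled (median -0.12) and with the mean of a gene's probe sets (median -0.08), which also ended the call of Idh2 (log2 -0.39). With array 3 alone, 8 of the 18 branched-chain genes and 2 of the 20 citrate cycle genes fell, with medians of -0.58 and -0.22.

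Unlike the citrate cycle list, the lists of fatty acid oxidation, oxidative phosphorylation and thermogenic markers did not pass the threshold in the main test. Among 22 fatty acid oxidation genes, 9 fell and 5 rose (11 and 5 adjusted over the list alone), with a median of -0.31 and a camera adjusted p of 0.156. Cpt1a, which controls fatty acid entry into mitochondria, rose 1.95-fold, and Hadha, of the trifunctional protein, rose 1.6-fold. The list passed the threshold without Pparg ldi/+ array 2 (median -0.34), with array 3 alone (-0.30) and with no filter on dim probe sets (-0.33). Among 45 oxidative phosphorylation genes, 4 fell and 2 rose (4 and 1 adjusted over the list alone), with a median of -0.04 and a camera adjusted p of 0.425. The complex I subunit genes Ndufb3 and Ndufb8 fell 1.69-fold and 1.32-fold, and the call of Ndufb8 ended with the mean of its probe sets (log2 -0.18). Of 10 tested thermogenic adipocyte markers, 2 rose and 1 fell (2 and 0 adjusted over the list alone). Their median was -0.07, their mean was 0.09 and camera pointed upward with an adjusted p of 0.792. Cox7a1 rose 3.14-fold and Kcnk3 rose 2.16-fold, and the member that fell was Cidea at -0.76.

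Of 22 transcription factors of adipogenesis tested, 12 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.000202; adjusted p = 0.255 with an estimated correlation). Pparg and Cebpa had the smallest p among them, and the 2 that rose were Egr2 at 1.91 and Cebpd at 0.42. Egr2 is also in the immediate early list.

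**Figure D2:**
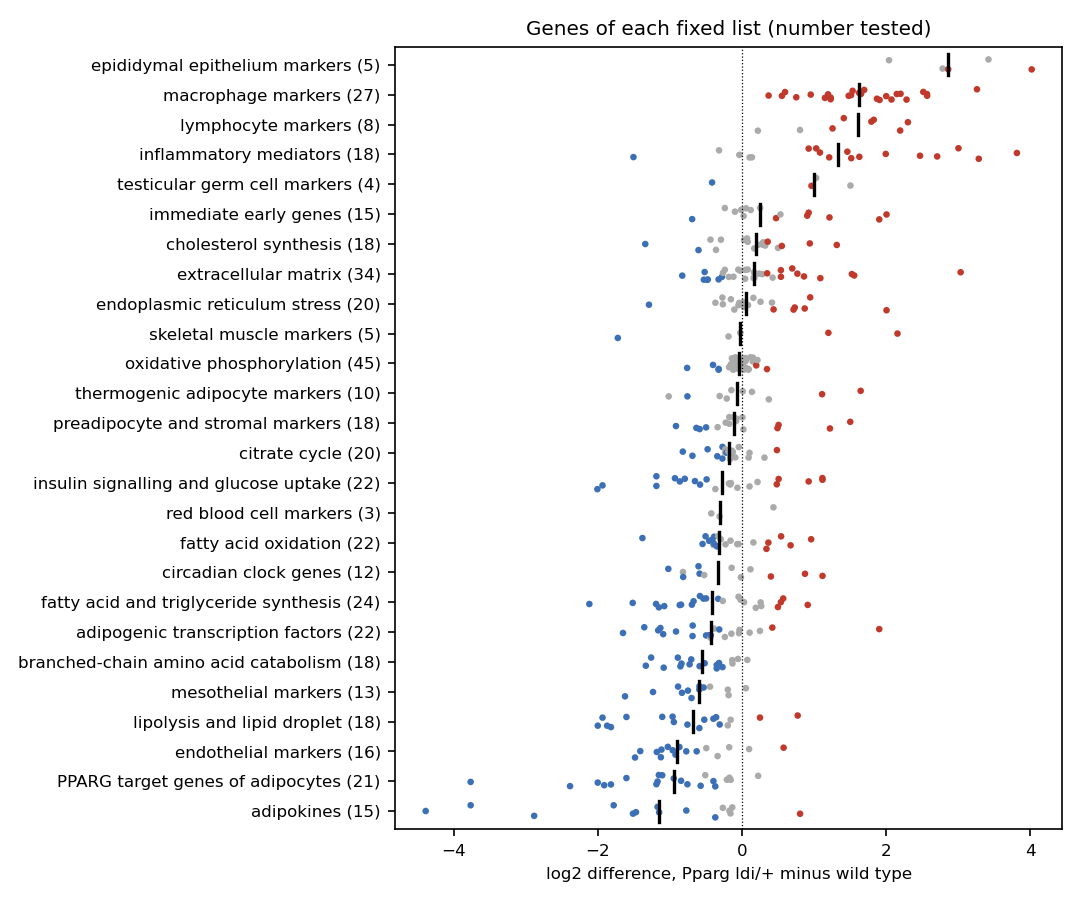
Differences of the tested genes of 26 lists. The horizontal axis is the log2 difference, Pparg ldi/+ minus wild type; each point is 1 gene, red where it rose and blue where it fell past the threshold and grey otherwise, and the vertical bar is the list's median. The adipokine list has the lowest median (-1.15), and the macrophage list has a median of 1.63 with all 27 points to the right of 0.

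Macrophage markers were higher in Pparg ldi/+ fat without exception in the list. All 27 genes tested rose, also adjusted over the list alone, with a median of 1.63 (camera adjusted p = 2.04e-18; adjusted p = 0.255 with an estimated correlation). Mpeg1 rose 5.94-fold (adjusted p = 4.34e-06), and the complement gene C1qb rose 3.24-fold, from 3422 ± 427 to 11125 ± 505 (adjusted p = 6.29e-06). With Pparg ldi/+ array 3 alone, which lacked the epididymal transcripts, 24 of the 27 rose and the median was 1.57. Of 8 lymphocyte markers, 6 rose, also adjusted over the list alone, with a median of 1.61 (camera adjusted p = 9.08e-05; adjusted p = 0.255 with an estimated correlation). Il7r, the interleukin-7 receptor gene, rose 4.59-fold and the B cell gene Cd22 rose 3.48-fold.

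Of 25 inflammatory mediators on the array, 18 were bright enough to be tested. Of these, 13 rose and 1 fell, also adjusted over the list alone. The median was 1.34 (camera adjusted p = 6.88e-05, and adjusted p = 0.361 with an estimated correlation). In wild type, Cxcl2, Cxcl10 and Il1b lay below the log2 cut of 7.46, at 6.74, 7.26 and 7.44. They passed the filter through their Pparg ldi/+ values of 8.37, 11.1 and 8.65, so the tested members favour rises. Cxcl10, an interferon-induced chemokine, rose 14.1-fold (adjusted p = 5.09e-06) and the adhesion molecule gene Vcam1 rose 6.55-fold (adjusted p = 3.72e-06). The member that fell was Orm1, an acute-phase protein gene, at -1.5. With array 3 alone, 5 of 17 rose and 1 fell, and the median was 0.97.

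Most markers of blood vessels and of the serosal surface fell. Of 16 endothelial markers, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 2.72e-06; adjusted p = 0.255 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, fell 2.79-fold and the junction gene Esam fell 2.18-fold; the member that rose was Plvap at 0.58. With array 3 alone, 12 of the 16 fell, and the median was -0.95. Of 13 mesothelial markers, 9 fell and 0 rose, also adjusted over the list alone, with a median of -0.59 (camera adjusted p = 0.000171; adjusted p = 0.260 with an estimated correlation). Msln, the mesothelin gene, fell 3.08-fold and the keratin gene Krt19 fell 2.35-fold. With array 3 alone, 2 of the 13 mesothelial markers fell, and the median was -0.54.

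The stromal and matrix lists did not pass the threshold in the main test. Of 18 preadipocyte and stromal markers, 4 rose and 4 fell, also adjusted over the list alone (median -0.10, camera adjusted p = 0.425). Those that rose were S100a4 (2.33-fold), Pdgfrb (1.41-fold), Dlk1 at 1.5 and Lum at 0.51, and those that fell were Pi16 at -0.91, Clec3b at -0.63, Dpp4 at -0.59 and Col14a1 at -0.50. Of 34 extracellular matrix genes, 10 rose and 7 fell (11 and 7 adjusted over the list alone). The median was 0.17, or 0.05 to 0.20 when any 1 array was left out, and the camera adjusted p was 0.176. Mmp12, the macrophage metalloelastase gene, rose 8.21-fold and Tnc (tenascin C) rose 2.88-fold. The matrix list passed the threshold with array 3 alone, at a median of 0.28.

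Marker genes of epididymal epithelium and of germ cells separated the Pparg ldi/+ arrays from each other. Of 10 epididymal epithelium genes on the array, 7 were at least 2-fold above the highest wild-type array in Pparg ldi/+ arrays 1 and 2, and 0 were in array 3. Lcn8 was at 5283, 7024 and 145 in arrays 1, 2 and 3, against 134 to 161 in wild type, and Gpx5 was at 4371, 5575 and 92.6 against 167 to 187. Lcn5 went the other way, with 457 in wild-type array 1 and at most 41.4 elsewhere. Of the 5 genes bright enough to be tested, Lcn9 and Rnase10 rose (3 rose adjusted over the list alone), and the list had a median of 2.86 and a camera adjusted p of 0.0571. Rnase10, 7.28-fold higher (adjusted p = 0.0461), lost its call in every fit that left out 1 array except the one without Pparg ldi/+ array 3, where it was at 4.22. Its log2 difference was 2.29 and 2.08 without Pparg ldi/+ array 1 or 2, 2.91, 2.95 and 2.74 without wild-type array 1, 2 or 3, and 0.15 with Pparg ldi/+ array 3 alone. The call also ended with no filter, with no intensity trend, with array weights and where genes were read as the mean of their probe sets. The list passed without Pparg ldi/+ array 3, at a median of 4.56, and with the deposited values left unscaled, at 2.70. Sperm and germ cell transcripts were high in Pparg ldi/+ array 2, where 10 of 12 were at least 2-fold above the highest wild-type array, against 0 in array 1 and 1 in array 3. The protamine gene Prm2 was at 1824 in Pparg ldi/+ array 2, and the highest of the other arrays was wild-type array 3 at 248.

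**Figure D3:**
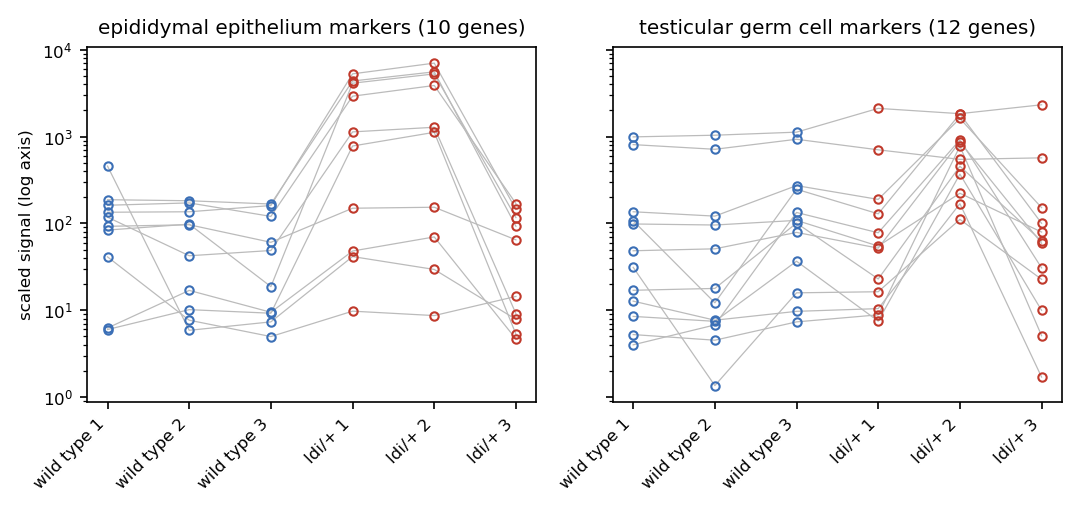
Scaled signals of epididymal epithelium and testicular germ cell genes on the 6 arrays. The vertical axis is logarithmic, each circle is 1 gene on 1 array (blue wild type, red Pparg ldi/+), and grey lines join a gene's values. The left panel shows 7 of 10 epididymal genes high in Pparg ldi/+ arrays 1 and 2 and not in array 3, and the right panel shows 10 of 12 germ cell genes high in array 2.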

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

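Signals outside the named genes were looked at only in a comparison of all probe sets, which had been planned. Of 2867 probe sets without a single gene symbol that were bright enough to be tested, 415 were higher and 334 were lower in Pparg ldi/+ fat (limma, Benjamini-Hochberg over 22519 probe sets). They stand out because no named comparison uses them, and their genes are not named here. With 3 arrays per group, no array was tested for standing apart from its group.

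The count of called genes was set against the other ways to divide the 6 arrays into 3 and 3, a test planned beforehand. Of the 10 splits, 1 gave as many calls as the 3668 of the real one, namely the real one itself, and the highest of the others gave 1. With 10 splits the share cannot be smaller than 1 of 10, so the test cannot reach 0.05. Each of the other splits puts both genotypes in each group, so the genotype difference widens the spread within groups. Their low counts therefore do not show how many calls arise by chance.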

How the results depend on the processing

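All alternatives except the comparison of Pparg ldi/+ array 3 alone were planned. Pparg fell past the threshold in each, with log2 differences of -1.26 to -1.40. The 70 named genes kept direction and side of the threshold in 1190 of their re-computed values, lost the call in 42, gained it in 5, moved in 1 and reversed in 1; for lists the numbers were 432 kept, 18 lost, 16 gained and 6 reversed. Leaving out 1 array gave 1290 to 1706 genes higher and 1447 to 1678 lower. Array 3 alone gave 730 higher and 886 lower, with fewer arrays, and testing all 22519 probe sets gave 3258 higher and 3273 lower, with more tests. Unscaled values gave 1792 higher and 1331 lower; no scaling moved the median of all genes by over 0.1. The number of lists higher, 3 in the main test, was 5 with unscaled values, 5 with array 3 alone, 5 with fry, and 3 to 5 when leaving out 1 array (5 without wild-type array 1, which added the endoplasmic reticulum stress and immediate early lists); it was 0 with an estimated correlation, as was the number lower, 0 in place of 10. For the called lists that setting replaced the preset 0.01 by larger correlations, estimated from 6 arrays. What the size of the estimates and the number of arrays each contributed to the lost calls was not tested. Fabp4 turned to 0.0299 with quantile normalisation. The thermogenic list, whose camera direction was upward, turned downward without any 1 of the Pparg ldi/+ arrays or without wild-type array 3, with medians from -0.192 to 0.190 over the fits that left out 1 array, and with array 3 alone at -0.188; the preadipocyte and stromal list turned upward in its test with array 3 alone at a median of -0.0905. The cause of these turns was not tested. With the mean of a gene's probe sets, Fdft1 (-0.44) and Ccn1 (0.53) lost their calls. Signal over background cannot be judged without detection calls, so dim genes are the least secure.

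Whether the numbers in the titles pair the samples could not be decided. The deviations of same-numbered arrays correlated at -0.13, -0.09 and -0.09, and no array correlated best with its own number. The deviations of the arrays of a genotype depend on each other, and so do these correlations. Weak correlations between single mice therefore cannot show whether the numbers mark litters. With the replicate block 1568 genes were higher and 1598 lower, and 5 lists were higher, the epididymal and immediate early lists being added; Odf2 was no longer called.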

Other observations

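Stress and early response genes rose in part. Of 20 endoplasmic reticulum stress genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.06 and a camera adjusted p of 0.153. Atf3, a stress-induced transcription factor, rose 4.02-fold (adjusted p = 6.29e-06), and the member that fell was Asns, the asparagine synthetase gene (2.44-fold). The list passed without wild-type array 1, at a median of 0.12, and by fry. Of 15 immediate early genes, 6 rose and 1 fell, also adjusted over the list alone, with a median of 0.25 and a camera adjusted p of 0.0556. Ccn1 rose 1.88-fold, though it no longer passed with the mean of its probe sets (0.53), and the member that fell was Btg2 at -0.69, named after its value was seen. The immediate early list passed without wild-type array 1 (median 0.44) and without Pparg ldi/+ array 2 (median 0.34). It also passed with unscaled values (0.28), with no filter on dim probe sets (0.34), with Pparg ldi/+ array 3 alone (0.29) and by fry. Of 12 circadian clock genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone, median -0.33, camera adjusted p = 0.394). The median of this list ranged from -0.45 to 0.04 when any 1 array was left out. Nr1d1, a repressor of the clock, fell 2.03-fold and Nfil3 rose 2.17-fold.

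Of 18 cholesterol synthesis genes, 4 rose and 2 fell, also adjusted over the list alone (median 0.20, camera adjusted p = 0.312). The list's median lay between 0.06 and 0.31 when any 1 array was left out. Lss rose 1.92-fold while Fdft1, which acts before it, fell 2.53-fold in the probe set read for it; with the mean of its probe sets Fdft1 was at -0.44 and no longer passed. Of 5 skeletal muscle markers, 2 rose and 1 fell, also adjusted over the list alone; the median was -0.02, the mean was 0.29, and camera pointed upward with an adjusted p of 0.581. Eno3 rose 4.47-fold and Myl1 fell 3.30-fold. Of 3 red blood cell markers, 0 passed, also adjusted over the list alone. Hbb-b2 was at -0.42 (adjusted p = 0.0984) and passed without wild-type array 1 (-0.58) and with the mean of its probe sets (-0.40). Slc4a1 was at 0.44 (adjusted p = 0.109) and passed with no intensity trend. Of 4 germ cell markers tested, 1 rose and 1 fell, also adjusted over the list alone. Sycp3 rose 1.95-fold and lay between 1837 and 2326 in the 3 Pparg ldi/+ arrays, against 992 to 1125 in wild type. Odf2 fell 1.33-fold, and its call ended without Pparg ldi/+ array 2 (-0.35) or 3 (-0.37) and without wild-type array 1 (-0.42) or 3 (-0.32). It also ended, among other settings, with unscaled values (-0.34), array weights (-0.37), the mean of its probe sets (-0.13), no filter on dim probe sets, no intensity trend and Pparg ldi/+ array 3 alone (-0.49).

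In the following, the test of the 200 genes beside Pparg was planned, the test on a second list of epididymal genes was chosen after the first list was seen, and the others were chosen after the values were seen; the bound for a genotype effect on epididymal genes was also revised then, so that a single array could not exclude it. Macrophage markers were higher while most PPARG target genes were lower. A lower share of adipocyte RNA raises the markers of every other cell type alike. The endothelial list argues against this as the whole cause, since its median was -0.89 and stayed between -0.95 and -0.86 when any 1 array was left out, while the macrophage median stayed between 1.5 and 1.78. An equal dilution of all adipocyte transcripts is also argued against, because the differences of 12 PPARG target genes, with the 9 brightest left out, had an SD of 0.946 where their median SE was 0.143. Brightness was judged by the mean over both genotypes, so Retn, at 14.3 in wild type, stayed in through its fall of -3.76 and widened the SD. The rest of the 12 ranged from -2.38 (Hcar1) to -0.37 (Angptl4). More macrophages, more transcript per macrophage and an effect of the genotype on adipocyte genes may each contribute and stay open as untested.

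Epididymal genes were high in Pparg ldi/+ arrays 1 and 2, where 7 of the 10 listed were at least 2-fold above the highest wild-type array, with signals up to 7024 for Lcn8 and 5575 for Gpx5 against at most 161 and 187 in wild type. RNA of the epididymis in 2 of the fat pads may be the source. Of 31 other epididymal genes, listed after this pattern was seen and before their own values were, 11 were on the array, and 5 of these (45.5%) were at least 2-fold above the highest wild-type array in both arrays and 0 in array 3, against 3.09% of all other genes in both (two-sided Fisher's exact p = 1.15e-05). High in both arrays and not in array 3 were 5 of the 11, against 162 of 18172 other genes. Fisher's test takes genes as independent, though all were read on the same mice, so its p does not measure the spread between mice. Among the 5 epididymal genes only Defb42 was bright, at 1323 and 1993. The others were dim, at 267 or less in either array, where signal over background cannot be judged. An effect of the genotype cannot be told apart from this with 3 animals, since the first list's median difference was 3.81 and 4.10 in 2 arrays and -0.167 in the other. The sperm transcripts of array 2 were not in array 1, with medians of 2.94 and 0.03 over the germ cell list.

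The Pparg locus was altered on a background of mixed strains, so that 129 strain sequence carried along with the targeted locus could alter the genes beside it. Of the 100 tested genes on each side of Pparg in assembly GRCm38.p6, 36.5% were called, against 32.7% of the other genes, a ratio of 1.12 (two-sided Fisher's exact p = 0.255). Differences of 2-fold or more made up 10.5% and 8.30% (Fisher's exact p = 0.247). In narrower windows, looked at after the first result, the share was 45% of the nearest 20 genes, 37.5% of 40 and 37.0% of 100 (unadjusted two-sided Fisher's exact p = 0.242, 0.504 and 0.392). The 200 genes argue only against linked sequence that greatly raises the calls over that whole stretch. A small rise cannot be excluded, because 32.7% of the other genes were called as well. An effect on the genes nearest to Pparg also stays open, since 20 genes are too few to exclude it.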
